A study of Mus musculus with 12 samples.

How the data were processed

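Bulk RNA sequencing was read from heart ventricles of 12 C57Bl/6J mice, 4 in each of 3 groups. Per the labels' protocols, RNA was isolated from snap-frozen ventricles with TRIzol and a column kit, and libraries were made and sequenced as read pairs at a commercial service. The deposited files hold whole-number counts per gene, one file per mouse. Per the submitters' processing notes, reads were aligned with HISAT2 and the counts were made with featureCounts. Versions, strand setting and the treatment of reads with several matches are not given in the sources used here. The same notes name the human build GRCh38, whereas the deposited count tables carry mouse Ensembl gene identifiers. Of 14957 identifiers, 14474 matched GENCODE vM21 (GRCm38) with their version and 14946 without it, so gene positions were taken from that annotation. The smallest total of a gene over all libraries was 30 counts, and every gene was above 0 in at least 6 libraries, so the deposited tables had passed a filter on low counts whose rule is not given in the sources used here. Mitochondrially encoded genes and transcripts of the vectors were not analysed here.

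Because the strand setting is not stated, reads of a gene and of a partner on the opposite strand cannot be told apart, and exons shared by neighbouring genes or near-identical copies make their counts uncertain. Near-identical copies among the named genes include Acta1 with other actins, Myh6 with Myh7, and members of the Klk1b, Ces1 and Serpinb1 families.

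Total counts ran from 5.36 to 11.5 M (mega-counts) per library. Samples were grouped by the mouse names in the labels. No pair of libraries in a group agreed within sampling noise (lowest chi-square per degree of freedom 5.35, over genes with at least 10 counts). Each mouse is a separate animal, so p-values of single genes measure the spread between animals.

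Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3, using limma 3.58.1 for list tests. Genes were kept with filterByExpr by group, which left 13910 and removed 1047. One quasi-likelihood model with robust dispersion was fitted to all 12 libraries with TMM scaling, and each pair of groups was compared two-sided with Benjamini-Hochberg adjustment over all genes tested. A gene was called below an adjusted p of 0.05. The common biological coefficient of variation was 0.203. Log2 fold changes carry a standard error (SE) derived as the size of the fold change divided by the square root of its quasi-likelihood F statistic. Intervals are 95% and built from that SE, and counts-per-million values (CPM) carry the SD over 4 libraries.

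Before the data were examined, 43 gene lists for processes, cell types and sample quality were fixed, along with 20 anchor genes and the rule for naming genes. Of the lists, 39 had at least 5 tested members and entered the tests. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, both adjusted over the 39 lists. The preset treats a list's genes as nearly independent, so its p-values do not measure the spread between animals. Estimated correlations in TAC-mScarlet against Sham-NT were 0.78 for the collagen and matrix list and 0.66 for oxidative phosphorylation. The fry test asked whether a list's genes moved one way on balance. For each library a list score was the mean log2(CPM + 1) of its members, compared between groups by an exact two-sided permutation test over 70 arrangements, whose smallest possible p is 0.0286. After adjustment over the lists scored, no list passed that test. Its smallest adjusted p was 0.0837 in TAC-mScarlet against Sham-NT, 0.586 in TAC-BacNav against TAC-mScarlet and 0.130 in TAC-BacNav against Sham-NT. With 4 against 4 libraries a list could pass only if many lists reached the smallest possible p together, so failing is no evidence of no difference. In TAC-mScarlet against Sham-NT several lists reached it, with no overlap of scores between the groups. Among them were the hypertrophic, collagen and matrix, TGF-beta, oxidative phosphorylation, fatty acid and ventricular cardiomyocyte lists. Named genes are the anchors, up to 10 called genes per direction with the largest change, a mean of at least 1 CPM, a regular symbol and no overlap between the groups, up to 4 called members per list and direction, up to 10 genes called in opposite directions by the first and second comparison, and, where fewer than 5 genes passed, the 5 with the smallest p. Genes outside this rule are said to have been chosen after their values were seen.

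On simulated counts for 13910 genes in 3 draws, the TAC-mScarlet against Sham-NT test recovered 15.9% of 1.5-fold, 65.2% of 2-fold and 92.4% of 4-fold changes with a mean of 6 false calls. The TAC-BacNav against TAC-mScarlet test recovered 17.4%, 66.2% and 92.4% with a mean of 8. Simulated counts varied independently from gene to gene, without the shared differences between libraries of a group, so these shares may not hold for the real libraries. Alternatives fixed in advance were DESeq2 1.42.0, limma-voom, DESeq2 size factors or library size in place of TMM, no filter or a filter of 1 CPM in 4 libraries, only the groups compared, the mouse number as a block, each library left out in turn and the estimated correlation. Alternatives added after the data were seen were a factor for a split of the libraries, fits within each side of that split, 1 surrogate variable from sva 3.50.0, thinning to equal depth and a transcript length covariate. Results of a few genes are not reported here, and these genes were left out of the counts over named genes but stayed in every fit and list.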

Results

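Ventricular transcripts were counted in 12 mice to assess gene therapy with BacNav, a bacterial voltage-gated sodium channel, in pressure overload. Sham-NT mice had a sham operation and received saline. TAC-mScarlet mice had transverse aortic constriction, which narrows the aorta and loads the left ventricle, and received an AAV9 vector with the fluorescent protein mScarlet under the muscle promoter MHCK7. TAC-BacNav mice had the same constriction and the same kind of vector carrying BacNav together with mScarlet. Each group held 4 mice. Total counts averaged 6.34 ± 1.14 M (mega-counts; SD, n = 4) in Sham-NT, 8.73 ± 0.723 M in TAC-mScarlet and 8.97 ± 1.79 M in TAC-BacNav. Every Sham-NT library (5.36, 5.55, 7.84 and 6.61 M) was shallower than every TAC-mScarlet library (8.28, 8.40, 9.81 and 8.45 M), and the TAC-BacNav libraries held 8.86, 8.16, 7.36 and 11.5 M.

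The libraries also differed within groups in immediate early genes, which respond within minutes to stress or handling. Fos ran from 54.9 to 301 CPM in 7 libraries (Sham-NT 1 and 2, TAC-mScarlet 1, 2 and 3, TAC-BacNav 1 and 2) and from 1.60 to 7.89 CPM in the other 5. Egr1 ran from 214 to 785 CPM against 16.3 to 35.03 CPM. The glucocorticoid-responsive gene Fkbp5 was opposite, at 17.8 to 24.4 CPM against 51.9 to 71.8 CPM, as was the clock gene Per2, at 15.3 to 51.6 CPM against 69.2 to 138 CPM. The mesothelial marker Msln ran from 11.9 to 28.4 CPM against 0.464 to 4.79 CPM. This split put 2 Sham-NT, 3 TAC-mScarlet and 2 TAC-BacNav libraries on its high side, and the counts of changed genes are therefore also given within each side. It was noticed in the data, and its genes were chosen after their values were seen.

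**Figure D1:**
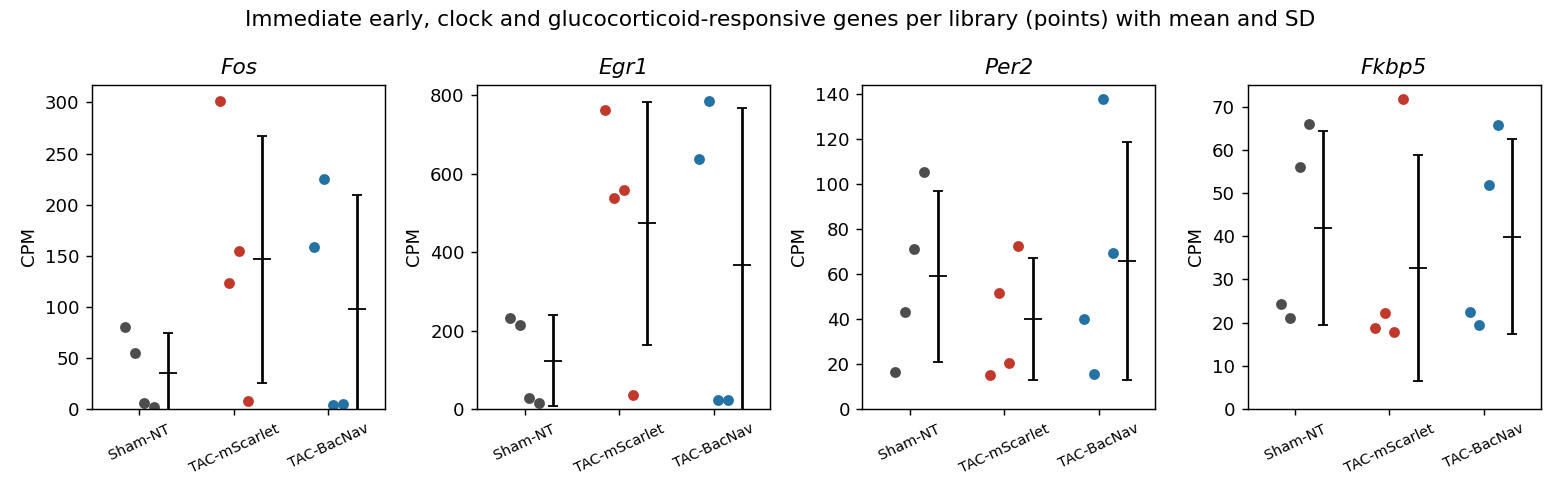
Normalised counts (CPM, linear axis) of Fos, Egr1, Per2 and Fkbp5 in each of the 12 libraries, by group, with the mean and SD of 4 libraries, the bars ending at 0 where the SD exceeds the mean. Fos lies between 54.9 and 301 CPM in 7 libraries and between 1.60 and 7.89 CPM in the other 5, within every group.

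Many genes of the hypertrophic and fetal cardiac programme were higher in TAC-mScarlet than in Sham-NT ventricles. Ankrd1 (ENSMUSG00000024803.9), a stretch-responsive ankyrin repeat protein of the sarcomere, averaged 5538 ± 1667 CPM (SD, n = 4) against 839 ± 135 CPM, a log2 fold change of 2.72 ± 0.24 (SE, adjusted p = 6.7e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Myh7 (ENSMUSG00000053093.16), the beta myosin heavy chain of the fetal heart, rose from 148 ± 13.9 to 748 ± 274 CPM (2.34 ± 0.30, adjusted p = 0.00406), while Myh6, the adult alpha chain, fell (-0.74 ± 0.20, adjusted p = 0.0442). The natriuretic peptide genes Nppa (ENSMUSG00000041616.9; 4.79 ± 0.83, adjusted p = 0.0229) and Nppb (2.16 ± 0.41, adjusted p = 0.0229) and the skeletal actin gene Acta1 (4.82 ± 0.83, adjusted p = 0.0229) rose as well, with Nppa at 1250 ± 1171 CPM and Acta1 at 5286 ± 1927 CPM against 44.9 ± 16.6 and 187 ± 72.3 CPM. Of 18 tested members of the hypertrophic list, 10 rose and 8 did not pass, and adjusted over the list alone 12 rose. They included Mybpc2, a myosin binding protein (1.57), and Xirp2, a protein of the intercalated disc (1.99). The list's median log2 fold change was 1.21 (camera adjusted p = 1.3e-15, and adjusted p = 0.0464 with an estimated correlation). On GRCm38, Ankrd1 lies on chromosome 19, 36111961 to 36120099, Nppa on chromosome 4, 148000722 to 148002079 and Myh7 on chromosome 14, 54970684 to 54994626. Nppa and Myh7 each have partners on the opposite strand, among them the long non-coding RNA Mhrt at Myh7.

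**Figure D2:**
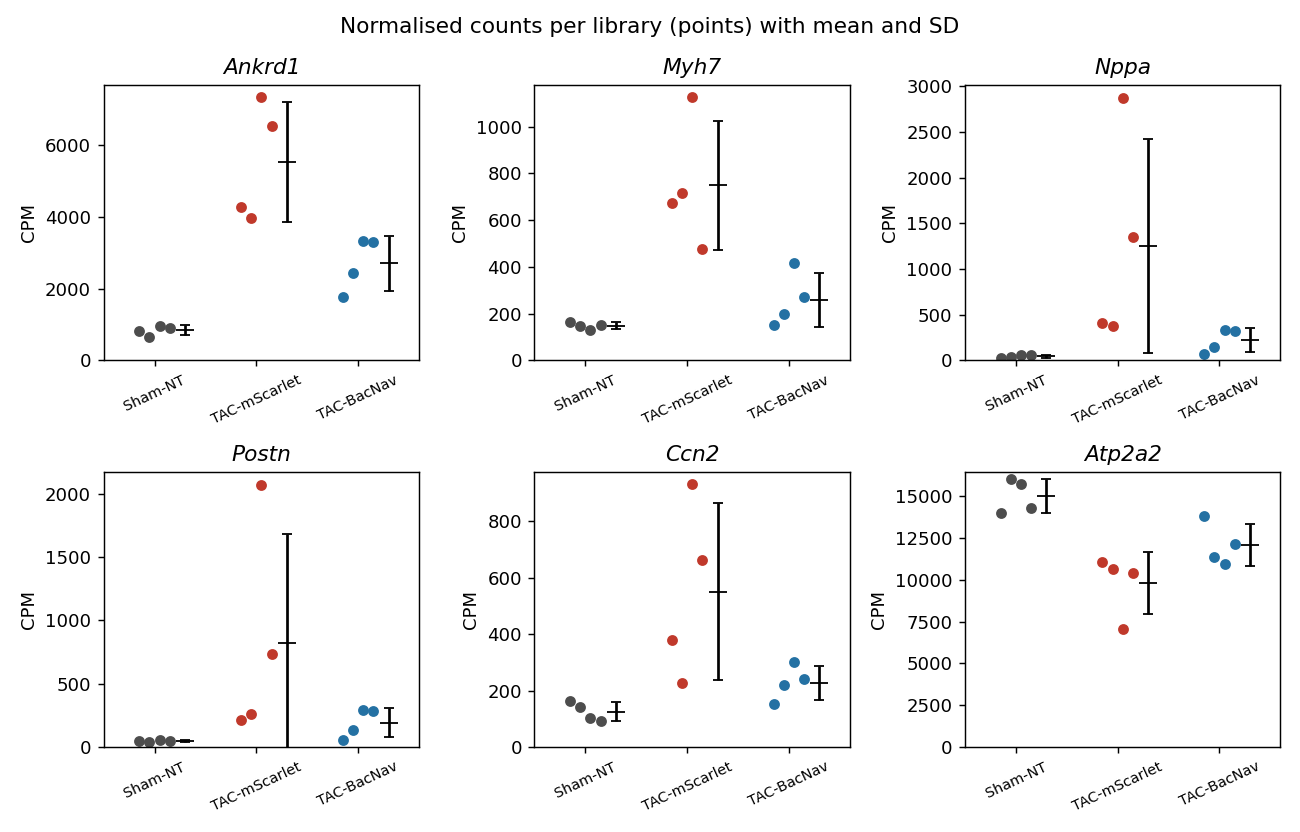
Normalised counts (CPM, linear axes from 0) of Ankrd1, Myh7, Nppa, Postn, Ccn2 and Atp2a2 in each of the 12 libraries, by group, with the mean and SD of 4 libraries, the lower bar ending at 0 for Postn. Ankrd1 averages 839 CPM in Sham-NT, 5538 ± 1667 CPM in TAC-mScarlet and 2703 ± 758 CPM in TAC-BacNav.

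Many genes of the extracellular matrix and of activated fibroblasts were higher in TAC-mScarlet. Postn, a matricellular protein made by activated fibroblasts, averaged 819.7 ± 864 CPM against 47.2 ± 5.55 CPM (4.12 ± 0.83, adjusted p = 0.0295). The matrix genes Cilp (4.66 ± 0.95), Thbs4 (4.33 ± 0.90), Col12a1 (4.45 ± 1.08) and Ltbp2 (4.19 ± 0.96) had adjusted p from 0.0300 to 0.0416. The collagen gene Col1a1 rose by 1.52 ± 0.33 (adjusted p = 0.0295), whereas Col3a1, at 1.59 ± 0.43, did not pass (adjusted p = 0.0573). Of 35 collagen and matrix genes 15 rose and 20 did not pass, and adjusted over the list alone 31 rose. Col8a1 (2.63), Bgn (1.69), Col14a1 (1.504) and Lum (1.16) were among them, and the median was 1.52 (camera adjusted p = 7.9e-24, but adjusted p = 0.238 with an estimated correlation). Of 11 activated fibroblast markers, 8 of which are also on the matrix list, 5 rose and 6 did not pass (8 rose adjusted over the list alone), with Meox1, a fibroblast transcription factor, at 2.07. Their median was 2.46 (adjusted p = 3.9e-06, and adjusted p = 0.291 with an estimated correlation). Of 16 general fibroblast markers 3 rose and 13 did not pass, with 9 up and 2 down adjusted over the list alone, a median of 0.58 and adjusted p = 0.00155 (0.370 with an estimated correlation, as adjusted p). Without TAC-mScarlet 3 the medians of the matrix, activated fibroblast and general fibroblast lists were 0.92, 1.56 and 0.36.

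Several genes of TGF-beta and CCN signalling were higher in TAC-mScarlet. The matricellular gene Ccn2 (2.14 ± 0.40, adjusted p = 0.0229), the activin subunit Inhba (1.85 ± 0.30, adjusted p = 0.0128), the ligand Tgfb2 (1.79) and the decoy receptor Bambi (0.94) rose, and Ltbp1 fell by 0.50 on the log2 scale. Of 19 members 7 rose, 1 fell and 11 did not pass, against 13 up and 1 down adjusted over the list alone. The median was 0.70 (camera adjusted p = 2.4e-13, and adjusted p = 0.0464 with an estimated correlation). The hypertrophic and TGF-beta lists were the only 2 of the 39 lists called with an estimated correlation, in this comparison or the other two, with all libraries. Both calls were lost (adjusted p = 0.0565 to 0.152) without Sham-NT 1, Sham-NT 2, Sham-NT 3, Sham-NT 4, TAC-mScarlet 1 or TAC-mScarlet 4.

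Many nuclear genes of mitochondrial energy metabolism were lower in TAC-mScarlet. Of 54 oxidative phosphorylation genes 23 fell and 31 did not pass, and adjusted over the list alone 49 fell. Examples were Ndufv1 of complex I (-0.63 ± 0.14), Uqcrc1 and Cyc1 of complex III (-0.62 ± 0.14 and -0.61 ± 0.13) and Cox7a1 of complex IV (-0.96 ± 0.21). The median was -0.57 with all 54 values below 0 (camera adjusted p = 2.2e-26, but adjusted p = 0.238 with an estimated correlation). Of 32 genes of fatty acid uptake and oxidation 12 fell and 20 did not pass (18 fell adjusted over the list alone), with a median of -0.52 (camera adjusted p = 4.7e-15, and 0.238 with an estimated correlation, as adjusted p). The thiolase Acaa2 (-1.17 ± 0.23, adjusted p = 0.0217), the electron transfer flavoprotein subunit Etfb (-1.403 ± 0.30, adjusted p = 0.0258), Eci1 (-0.82) and Acot2 (-0.96) fell, as did Ppargc1a, a coactivator of mitochondrial biogenesis (-0.89 ± 0.23, adjusted p = 0.0426). Cpt1b, the muscle carnitine palmitoyltransferase, gave -0.79 ± 0.53 (adjusted p = 0.417) at about 1 CPM, and its exons overlap another gene. In the tricarboxylic acid cycle 2 of 19 genes fell, Suclg1 (-0.70) and Idh3g (-0.55), and 10 fell adjusted over the list alone (median -0.35, adjusted p = 3.9e-07, and adjusted p = 0.370 with an estimated correlation). In glycolysis 5 of 21 genes fell, and adjusted over the list alone 8 fell and 1 rose. They included the enolase Eno3 (-0.79), Pkm (-0.49), Ldhb (-0.60) and Pfkfb1 (-2.45 ± 0.37, adjusted p = 0.00986), which shares its opposite strand with Apex2. The glycolysis median was -0.26 (adjusted p = 4.0e-04, and adjusted p = 0.238 with an estimated correlation). In branched-chain amino acid breakdown 4 of 18 genes fell, Bckdhb (-0.68) among them, with 6 down adjusted over the list alone (median -0.29, adjusted p = 4.9e-05, and adjusted p = 0.440 with an estimated correlation). Oxidative phosphorylation genes also moved in a split by depth that partly follows the groups. In the Sham-NT and TAC-BacNav libraries combined, the 4 deeper libraries (3 of them TAC-BacNav) had an oxidative phosphorylation median -0.33 from that of the 4 shallower (3 of them Sham-NT), and a ribosomal protein median of -0.42. With a transcript length covariate, added after the data were seen, the oxidative phosphorylation median of TAC-mScarlet against Sham-NT was -0.44 and 6 genes of that list fell.

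Contractile and ion transport genes were called in both directions. Atp2a2, the sarcoplasmic reticulum calcium pump, fell from 15034 ± 1001 to 9804 ± 1847 CPM (-0.62 ± 0.15, adjusted p = 0.0323), and Hrc, its calcium-binding partner in the reticulum, fell by 0.67 on the log2 scale (adjusted p = 0.0381). These were the 2 of 33 calcium handling genes called (1 up and 4 down adjusted over the list alone). The ryanodine receptor gene Ryr2 gave -0.65 ± 0.20 (adjusted p = 0.0663), phospholamban, Pln, gave -0.31 ± 0.15 (adjusted p = 0.248), the sodium/calcium exchanger gene Slc8a1 gave -0.14 ± 0.12 (adjusted p = 0.565) and Camk2d gave -0.14 ± 0.10 (adjusted p = 0.477). The calcium handling list was not called (median -0.15, camera adjusted p = 0.226). Of 20 sodium transport genes 1 rose, 1 fell and 18 did not pass, with the same counts adjusted over the list alone (list adjusted p = 0.564). Of 26 potassium channel genes Kcnv2 (-1.89), Kcnd2 (-0.85) and Kcnk3 (-0.68) fell and 23 did not pass, with 6 down and 1 up adjusted over the list alone (median -0.37, -0.21 without TAC-mScarlet 3, adjusted p = 3.4e-04, and adjusted p = 0.370 with an estimated correlation). The gap junction gene Gja1 gave 0.35 ± 0.23 (adjusted p = 0.409). Among 19 intercalated disc genes Xirp2, Nrap (0.93) and Des (0.55) rose and Dsg2 (-0.91) and Ctnna1 (-0.41) fell, against 4 up and 4 down adjusted over the list alone (list adjusted p = 0.599). Among 25 sarcomere genes Myh7 and Myom3 (1.14) rose and Tnni3 (-0.93), Tnnt2 (-0.48) and Myh6 fell, against 4 up and 7 down adjusted over the list alone (list adjusted p = 0.379). The sarcomere median was -0.09 and the sodium transport median -0.04 with TMM, and with library size scaling they were 0.034 and 0.077.

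Of 20 macrophage and monocyte markers 5 rose and 15 did not pass (8 rose adjusted over the list alone). Adgre1, which encodes the macrophage surface protein F4/80, rose by 0.87, the lysozyme gene Lyz2 by 0.64 and Fcgr1 by 1.86, and the list's median was 0.46, or 0.27 without TAC-mScarlet 3 (adjusted p = 1.9e-04, and adjusted p = 0.440 with an estimated correlation). Of 14 ventricular cardiomyocyte markers 3 fell, Tnni3, Tnnt2 and Myh6, all of which are also sarcomere genes, and 9 fell adjusted over the list alone (median -0.48, adjusted p = 4.2e-05, and adjusted p = 0.238 with an estimated correlation). Of 7 B cell markers tested, from a list of 12, 0 were called and 1 rose adjusted over the list alone (median 1.05, camera adjusted p = 0.0318, and adjusted p = 0.460 with an estimated correlation). Endothelial markers had a median of 0.11 (adjusted p = 0.421), and smooth muscle and pericyte markers of -0.10 (adjusted p = 0.664), which was 0.031 with library size scaling. Among single called genes of other lists were Rcan1, a target of calcineurin (1.63 ± 0.33, adjusted p = 0.0245), the survival gene Bcl2 (27.1 ± 9.12 against 10.2 ± 0.814 CPM), the superoxide dismutase genes Sod1 (-0.70) and Sod2 (-0.52), and the vascular growth factors Vegfc (0.88) and Vegfb (-0.54). The largest increases outside the lists included Atp6v0a4, a proton pump subunit with 7, 29, 77 and 57 counts against 1, 1, 0 and 0 (adjusted p = 0.0150), too few for a fold, Serpinb1c (4.79) and Dio2, which activates thyroid hormone (4.42 ± 0.97, adjusted p = 0.0343). The largest decreases were Rgs7 (-3.20), Tmprss13 (-2.91), Klk1b26 (-2.88), Rp1 (-2.86), Pfkfb1, the G protein-coupled receptor gene Mas1 (-2.41), Lgals4 (-2.35), Tbc1d10c (-2.24), Sbk2 (-2.24) and Ces1e (-2.12).

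In all, 719 of 13910 genes differed between TAC-mScarlet and Sham-NT, 369 higher and 350 lower, of which 172 and 84 changed at least 2-fold, and 17 of 39 lists were called. Unadjusted fry p was also below 0.05 for 17 of the 39 lists, though not the same 17. They included collagen and matrix (0.0121), oxidative phosphorylation (0.00402) and fatty acid genes (0.00253), whereas macrophage markers (0.0557) did not reach it. At an unadjusted p below 0.05 there were 3092 genes against 695.5 expected by chance, and 1824 genes (13.1%, against 2.86% by chance) had no overlap between the groups' libraries. With library size scaling, 903 genes were called, 698 higher and 205 lower, and the median of all genes shifted by 0.131, so changes are given relative to TMM. Within the high side of the immediate early gene split (3 TAC-mScarlet and 2 Sham-NT libraries) 692 genes were called, 282 of them among the 719, and within the low side (1 and 2 libraries, with the lone one assumed to vary like the others) 96 were called, 63 of them among the 719. The count depended on single libraries: it was 14 without Sham-NT 2, 20 without Sham-NT 4, 97 without TAC-mScarlet 3, 228 without TAC-mScarlet 4 and 256 without Sham-NT 1. All 719 genes kept their sign in each of these fits, but they had been chosen from the same libraries, so this is no independent support. Called in all 8 fits that left out 1 library were 13 genes, among them Ankrd1, Myh7, Mybpc2 and Pfkfb1, and each other called gene named above lost its call in at least 1 fit. Constriction and vector changed together in this comparison and cannot be separated. DESeq2 called 1371 genes and limma-voom 467.

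TAC-BacNav against TAC-mScarlet compares BacNav with the control vector under the same constriction. Among the lower genes with the smallest p were Myh7 and Ankrd1, both of which were higher in TAC-mScarlet than in Sham-NT. Myh7 averaged 259 ± 115 CPM (SD, n = 4) in TAC-BacNav against 748 ± 274 CPM (log2 fold change -1.53 ± 0.29, SE) and Ankrd1 2703 ± 758 against 5538 ± 1667 CPM (-1.03 ± 0.23). Neither passed edgeR's test after Benjamini-Hochberg adjustment in the fit without further factors, with adjusted p of 0.780 and 0.855, although Ankrd1 was called with mouse number as a block. The interferon-inducible GTPase gene Igtp had the smallest p among higher genes, at 41.4 ± 14.6 against 16.7 ± 3.39 CPM (1.31 ± 0.24, adjusted p = 0.780), and its exons overlap those of Irgm2. Bmper (0.96 ± 0.21) and Apex2 (1.10 ± 0.25), which overlaps Pfkfb1, each had an adjusted p of 0.855, and Myorg (0.66), Tmprss13 (2.29), Lrrcc1 (-0.64) and Prkab2 (-0.53) followed.

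Of the 13910 genes, 0 were called by edgeR between TAC-BacNav and TAC-mScarlet in the fit of all 12 libraries without further factors (smallest adjusted p = 0.780). At an unadjusted p below 0.05 there were 467 genes, 192 higher and 275 lower, below the 695.5 that chance gives. DESeq2 called 5 genes (3 lower, Ankrd1 and Myh7 among them, and Igtp and BC023105 higher) and limma-voom 0. Within the split, the high side (2 TAC-BacNav and 3 TAC-mScarlet libraries) gave 2 calls, Myh7 and Mir6236, and the low side (2 and 1) gave 0. BC023105 and Mir6236 were named after their values were seen. No overlap between the groups' libraries was seen for 236 genes (1.70%, against 2.86% by chance). Other anchor genes had an adjusted p of 1.00 in this comparison. Their log2 fold changes were -2.52 ± 0.74 for Nppa (95% interval -4.18 to -0.85), -0.66 ± 0.39 for Nppb, -0.82 ± 0.71 for Acta1, -2.10 ± 0.76 for Postn, -1.28 ± 0.38 for Ccn2, -0.67 ± 0.33 for Col1a1 and -0.70 ± 0.42 for Col3a1. For ion and energy genes they were 0.30 ± 0.15 for Atp2a2 (95% interval -0.02 to 0.62), 0.18 ± 0.12 for Slc8a1 (-0.08 to 0.45), 0.19 ± 0.20 for Ryr2, 0.12 ± 0.15 for Pln, -0.00 ± 0.10 for Camk2d, -0.36 ± 0.23 for Gja1, 0.50 ± 0.21 for Kcnd2, 0.51 ± 0.20 for Myh6, 0.72 ± 0.23 for Ppargc1a and 0.20 ± 0.53 for Cpt1b.

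As sets, 13 of 39 lists were called in TAC-BacNav against TAC-mScarlet with the preset correlation, 4 lower and 9 higher, and 0 with an estimated correlation. Unadjusted fry p was below 0.05 for 3 lists, hypertrophic (0.0190), TGF-beta (0.0181) and glycolysis (0.0316). The exact permutation p of the score was 0.0286 for TGF-beta genes and for atrial and sinus node markers (adjusted p = 0.586 for each). Adjusted over the list alone, 7 of 18 hypertrophic genes and 3 of 19 TGF-beta genes were lower, with medians of -0.63 (camera adjusted p = 4.3e-10, adjusted p = 0.140 with an estimated correlation) and -0.35 (6.0e-09 and 0.140, the same adjusted p values). Collagen and matrix genes had a median of -0.70 with 34 of 35 values below 0 (adjusted p = 1.2e-18, and adjusted p = 0.474 with an estimated correlation), and activated fibroblast markers of -1.60 (adjusted p = 2.7e-04, and adjusted p = 0.571 with an estimated correlation). All 54 oxidative phosphorylation genes had values above 0, with a median of 0.19 (adjusted p = 2.3e-09, and adjusted p = 0.662 with an estimated correlation). Fatty acid genes had a median of 0.19 (adjusted p = 3.0e-06, and adjusted p = 0.571 with an estimated correlation), as had the tricarboxylic acid cycle (adjusted p = 2.7e-06, and adjusted p = 0.571 with an estimated correlation). Potassium channels had a median of 0.20 (adjusted p = 6.3e-04, and adjusted p = 0.571 with an estimated correlation). Cell-type markers moved with them: ventricular cardiomyocyte markers had a median of 0.12 (adjusted p = 0.0141, and adjusted p = 0.571 with an estimated correlation) and smooth muscle and pericyte markers of 0.14 (adjusted p = 0.00685, and adjusted p = 0.474 with an estimated correlation). The first was not called without TAC-mScarlet 3 (median 0.07), TAC-mScarlet 4 or TAC-BacNav 1 (0.06) and was 0.19 without TAC-mScarlet 1. The second was not called without TAC-mScarlet 1 (0.09) or TAC-BacNav 4 and was 0.21 without TAC-mScarlet 2. Single libraries carried much of the other medians. Without TAC-mScarlet 3 these were -0.26 for matrix, -0.46 for activated fibroblast, -0.17 for TGF-beta, 0.07 for fatty acid, 0.09 for tricarboxylic acid cycle and 0.13 for potassium channel genes, and the fatty acid and potassium channel lists were no longer called. Without TAC-BacNav 1 the oxidative phosphorylation, fatty acid and tricarboxylic acid cycle medians were 0.10, 0.11 and 0.11, and potassium channels were not called. Without TAC-mScarlet 4 the TGF-beta median was -0.23, without TAC-BacNav 4 the oxidative phosphorylation median was 0.30, and without TAC-mScarlet 2 the hypertrophic list was called with an estimated correlation (adjusted p = 0.0403). The sodium transport list (median 0.06, adjusted p = 0.616) and the calcium handling list (median 0.03, adjusted p = 0.390) were not called. Counted over all genes, 0 members of any list passed edgeR's test in this comparison in the fit without further factors, against 467 genes in all at an unadjusted p below 0.05 and 5 by DESeq2. With mouse number as a block edgeR called 6 genes, among them Ankrd1, Nppa and Col12a1.

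**Figure D3:**
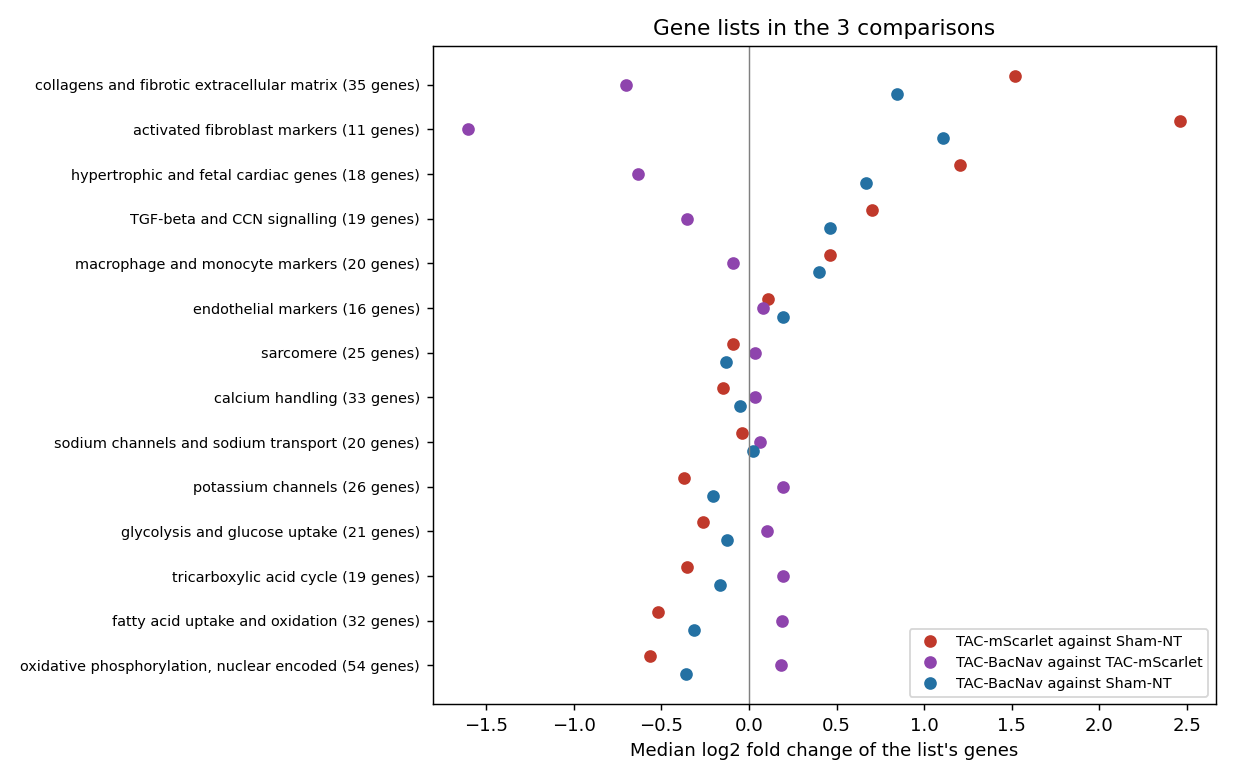
Median log2 fold change of the tested genes of 14 lists in TAC-mScarlet against Sham-NT, TAC-BacNav against TAC-mScarlet and TAC-BacNav against Sham-NT, with the number of genes beside each name. The collagen and matrix medians are 1.52, -0.70 and 0.84, and those of oxidative phosphorylation are -0.57, 0.19 and -0.36.

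Of the 719 genes that differed between TAC-mScarlet and Sham-NT, 712 (99.0%, exact 95% interval 98.0 to 99.6, treating genes as independent) had their TAC-BacNav mean on the Sham-NT side of the TAC-mScarlet mean. None of them, 0 of 719, was called in the opposite direction between TAC-BacNav and TAC-mScarlet by edgeR in the fit of all 12 libraries without further factors. Since that comparison called 0 genes, this count and the overlap expected of independent lists were both 0 by definition and test nothing. Counted anew in other fits, such genes numbered 4 by edgeR with mouse number as a block, 1 with a surrogate variable and 2 on the high side of the split, 4 by DESeq2 and 0 by limma-voom. The TAC-mScarlet libraries stand in both comparisons, so shared chance values alone put many genes there. With unchanged groups simulated 20 times, 88.6% (85.1 to 91.4) of the 719 genes with the smallest p did so. No gene differed between the simulated groups, 0 were called in any draw, and genes varied independently of each other. That share therefore need not hold for genes that do differ between TAC-mScarlet and Sham-NT. The correlation of the fold changes across genes was -0.69 against -0.48 in the simulation, and the covariance -0.0991 against -0.0403, a difference of -0.0588. With the TAC-mScarlet libraries split into 2 and 2, so that the comparisons shared none, the share among the top 719 genes was 82.6, 77.5, 88.5, 80.1, 87.5 and 59.7% in the 6 arrangements, a mean of 79.3%, and the covariance averaged -0.0644. The lowest share came with TAC-mScarlet 3 and 4 set against Sham-NT.

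The sarcomere gene Ankrd1 was higher in TAC-BacNav than in Sham-NT ventricles. It averaged 2703 ± 758 against 839 ± 135 CPM (SD, n = 4; log2 fold change 1.69 ± 0.24, adjusted p = 0.0401, edgeR with Benjamini-Hochberg adjustment). In all 2 genes were called, both higher, while 1544 genes had an unadjusted p below 0.05 (695.5 expected) and 758 (5.45%, against 2.86% by chance) had no overlap between the groups. Higher genes that did not pass included Crispld2 (0.72 ± 0.12, adjusted p = 0.0914) and the integrin gene Itgb8 (1.76 ± 0.33, adjusted p = 0.230), followed by Ier5 (0.99), Met (1.27) and Tiparp (0.75). The lower genes with the smallest p were Etfbkmt (-0.68), Rgs2 (-1.20), Egflam (-0.87), Pim3 (-0.76) and Tnnt1 (-0.65), with adjusted p from 0.319 to 0.321. Among anchors, Acta1 gave 4.00 ± 0.80, adjusted p = 0.344, Nppa 2.27 ± 0.75, adjusted p = 0.372, Nppb 1.505 ± 0.40, adjusted p = 0.367, Postn 2.01 ± 0.77, adjusted p = 0.409 and Myh7 0.80 ± 0.29, adjusted p = 0.385. Atp2a2 gave -0.32 ± 0.15, adjusted p = 0.454, Myh6 -0.24 ± 0.20, Ccn2 0.86 ± 0.38, Col1a1 0.84 ± 0.33, Col3a1 0.89 ± 0.42, Ryr2 -0.46 ± 0.20, Pln -0.19 ± 0.15, Slc8a1 0.05 ± 0.12, Gja1 -0.01 ± 0.23, Kcnd2 -0.35 ± 0.20, Camk2d -0.14 ± 0.10, Ppargc1a -0.17 ± 0.23 and Cpt1b -0.59 ± 0.52, and adjusted p ran up to 0.994.

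With the preset correlation 21 of 39 lists were called between TAC-BacNav and Sham-NT, and 0 with an estimated correlation. Unadjusted fry p was below 0.05 for 10 of the 39 lists, oxidative phosphorylation (0.0254) among them, but not for collagen and matrix genes (0.0837). Collagen and matrix genes had a median of 0.84 (adjusted p = 1.3e-13, and adjusted p = 0.394 with an estimated correlation). For hypertrophic genes it was 0.67, with Ankrd1 called and 8 of 18 higher adjusted over the list alone (adjusted p = 1.4e-10, and adjusted p = 0.132 with an estimated correlation). For TGF-beta genes it was 0.46, with 1 called and 4 higher and 1 lower adjusted over the list alone (adjusted p = 3.0e-08, and adjusted p = 0.132 with an estimated correlation). For oxidative phosphorylation it was -0.36 (adjusted p = 1.3e-21, and adjusted p = 0.384 with an estimated correlation), and for fatty acid genes -0.32, with 9 of 32 lower adjusted over the list alone (adjusted p = 1.1e-11, and adjusted p = 0.384 with an estimated correlation). Macrophage markers had a median of 0.40 and 5 of 20 higher adjusted over the list alone (adjusted p = 5.9e-07, and adjusted p = 0.384 with an estimated correlation). Ventricular cardiomyocyte markers had a median of -0.29 (adjusted p = 5.1e-04, and adjusted p = 0.384 with an estimated correlation), and activated fibroblast markers of 1.11 (adjusted p = 4.8e-05, and adjusted p = 0.384 with an estimated correlation), or 1.76 without Sham-NT 1 and 1.81 without TAC-BacNav 1. Ribosomal protein genes had a median of -0.22 (adjusted p = 5.1e-04, and adjusted p = 0.566 with an estimated correlation), or -0.14 without Sham-NT 2, -0.37 without Sham-NT 3 and -0.13 without TAC-BacNav 4. Immediate early genes had a median of 0.92 (adjusted p = 0.00111, and adjusted p = 0.533 with an estimated correlation) and were not called without Sham-NT 3 or TAC-BacNav 1. The other lists named here stayed called, with medians within 1.5 times, whichever library was left out, whereas over all 21 lists 10 stayed called and 9 medians moved further. The count of lists was 11 without Sham-NT 3 and 13 without TAC-BacNav 3. The count of genes was 0 without Sham-NT 1, Sham-NT 3, Sham-NT 4, TAC-BacNav 2 or TAC-BacNav 3, 1 without Sham-NT 2 or TAC-BacNav 4 (Ier5 in the latter), and 15 without TAC-BacNav 1. Within the split, 4 genes were called on the high side (Xirp1, Ndufb2, Etfb and Egr1, named after their values were seen) and 34 on the low side, each from 2 against 2 libraries, and DESeq2 called 38 over all libraries. With library size scaling the median of all genes shifted by 0.105 in this comparison, and the same 2 genes were called.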

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

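The tests of depth, of transcript length, of cell share, of short transcripts and of single TAC-mScarlet libraries below were chosen after the data were seen; those of other groupings and of shared libraries were fixed before.

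The calls between TAC-mScarlet and Sham-NT were weighed against grouping by chance, depth and transcript length. Only 1 of the 35 ways to split the 8 libraries 4 and 4 gave as many genes, the real one with 719, and the highest of the others gave 1. That share, 2.86%, is the smallest that 35 splits can give, so chance was unlikely for this count but not excluded. With every library thinned to one total, 607 of the 719 were called again, which argues against unequal sampling noise as the whole cause. Thinning leaves in place any other difference between libraries that goes with depth, so it could not test such a difference. With the transcript length slope as a covariate 442 were called again, between the bounds set before that fit, so length bias between libraries stays open for part of the calls. All 719 kept their sign there, but were chosen from the same libraries. A response to constriction or to the vector, which the design confounds, stays open beside it as an untested hypothesis.

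Lower oxidative phosphorylation genes in TAC-mScarlet could come from a smaller share of cardiomyocyte RNA or from short transcripts being counted less. For a loss of cardiomyocytes that raises every other cell type alike, the fibroblast score changed by 0.474 and that of smooth muscle and pericytes by -0.076, a difference of 0.550 with no overlap (exact permutation p = 0.0286, the smallest possible). The fibroblast list shares 5 genes with the collagen and matrix list, whose median rose by 1.52. The difference therefore cannot tell cell share from raised matrix genes, and such a loss stays open. The oxidative phosphorylation score fell further than the sarcomere score (difference -0.526, exact permutation p = 0.0286), but that list holds Myh7, which rose with hypertrophy, and the score of ventricular cardiomyocyte markers fell by 0.379, leaving a difference of -0.153 (exact permutation p = 0.200), so a smaller share through RNA added by fibroblasts stays open. Against short transcripts as the whole cause, the oxidative phosphorylation score fell further than the score of ribosomal proteins, whose transcripts are also short, by -0.398 (exact permutation p = 0.0286), although the length covariate took the list's called genes from 23 to 6 and its median from -0.57 (median SE 0.157) to -0.44 (0.137), with a smaller fold change in each of the 17 genes that lost their call (median -0.69 to -0.51) and a larger SE in 0. Lower transcription of these genes in TAC-mScarlet remains a hypothesis, and an RNA loss tied to library preparation was not tested.

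The share of 99.0% counts genes of the 719 whose TAC-BacNav mean lay on the Sham-NT side of the TAC-mScarlet mean, by any distance. It was weighed against shared libraries and single libraries. Leaving out any 1 TAC-mScarlet library gave at least 97.9%. Shared libraries alone gave 88.6% where simulated groups did not differ, and a simulation with a real difference between TAC-mScarlet and Sham-NT was not run. This measure therefore cannot tell whether a single library carried the share. With no shared libraries the mean share was 79.3% and the lowest, with TAC-mScarlet 3 and 4 against Sham-NT, 59.7%, between the bounds set in advance. The simulated 88.6% holds for shared libraries only and is no reference for these shares. The covariance was negative in each of the 6 arrangements (-0.0878 to -0.0195), which argues against sharing as the whole cause. These arrangements reuse the same 4 TAC-mScarlet libraries, so an effect of BacNav cannot be told apart from differences between single mice.

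Between TAC-BacNav and TAC-mScarlet the real count was 0, which each of the 35 splits reaches by definition, so the splits test nothing there. The highest of the others gave 137, pointing to a structure of the samples, for TAC-mScarlet 1 and 2 with TAC-BacNav 1 and 2 against the rest, which but for TAC-mScarlet 3 is the immediate early gene split, and fits within that split's sides gave 2 (high) and 0 (low) genes. The other counts were reached by other splits as well. Between TAC-BacNav and Sham-NT 3 of 35 gave 2 genes or more. The highest, 611, points to a structure of the samples, since that split separates the 4 deepest from the 4 shallowest of these libraries, although it follows the groups but for Sham-NT 3 and TAC-BacNav 3, and the immediate early gene split itself gave 87, with 4 (high) and 34 (low) genes called within its sides. Lists numbered as many in 7 of 35 splits between TAC-mScarlet and Sham-NT (real 17, highest other 21), in 16 of 35 between TAC-BacNav and TAC-mScarlet (13 and 20) and in 2 of 35 between TAC-BacNav and Sham-NT (21 and 22).

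In 456 groups of 4 values tested, 29 had 1 library far from the other 3, where chance gives about 22.8. Of these, 10 were in Sham-NT 3 and 8 in TAC-mScarlet 3. Sham-NT 3 stood apart for Col8a1 (41.4 CPM), Cox7a1 (757), Etfb (119.6), Itgb8 (0.776), Kcnd2 (36.0), Map1lc3a (539.5) and Rgs2 (67.8), and for the scores of endothelial markers (6.696), glycolysis (8.24) and sodium transport (5.57). TAC-mScarlet 3 did so for Atp2a2 (7061 CPM, the others 10435 to 11051), Myh6 (4764, the others 9208 to 9315), Nrap (508), Lum (253), Lyz2 (655), its total count (9.81 M) and the adipocyte (5.01) and interferon (4.497) scores. Sham-NT 1 did so for Fcgr1 (3.57 CPM), Nppb (575) and Pnpla2 (251), and Sham-NT 2 for Thbs4 (3.32) and the hypertrophic score (6.59). TAC-BacNav 1 stood apart for Col1a1 (60.7 CPM), Egflam (24.9) and the smooth muscle score (5.29) and TAC-BacNav 4 for Ifit2 (36.6), Sod1 (250.4) and the ribosomal protein score (8.60).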

How the results depend on the processing

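The split factor, the fits within its sides, the surrogate variable, thinning to equal depth, the length covariate and the reading of single lists without a library were chosen after the data were seen, and the cause of a changed value was not tested except where stated. The 719 calls of TAC-mScarlet against Sham-NT became 1371 with DESeq2, 467 with limma-voom, 1459 with the split factor, 1259 with a surrogate variable, 96 on the low side (fewer libraries) and 14 to 1055 with 1 library left out (14 without Sham-NT 2, 20 without Sham-NT 4, 97 without TAC-mScarlet 3, 228 without TAC-mScarlet 4, 256 without Sham-NT 1), and stayed within 1.5 times elsewhere (690 at equal depth, 530 with the length covariate). All of the 719 that could be tested kept their sign in every fit (704 at equal depth and 707 with only these groups), which is no independent support, since they were chosen from the same libraries. The 0 calls of TAC-BacNav against TAC-mScarlet became 5 with DESeq2, 1 with only these groups (BC023105), 1 with a surrogate variable (Egr2) and 2 on the high side. The 2 calls against Sham-NT became 38 with DESeq2, 1 with only these groups, 8 with the split factor, 0 with the length covariate, 11 with a surrogate variable, 4 on the high side, 34 on the low side and 0 to 15 with 1 library left out (15 without TAC-BacNav 1). Genes called in opposite directions went from 0 to 4 with DESeq2, 1 with a surrogate variable and 2 on the high side. The share on the Sham-NT side of the TAC-mScarlet mean was 97.4% with DESeq2, 96.8% with a surrogate variable, 91.2% on the high side and 93.7 to 100% with 1 library left out. Called lists fell from 17, 13 and 21 to 2, 0 and 0 with an estimated correlation, rose to 20 in TAC-BacNav against TAC-mScarlet with the length covariate, and were 11 to 22 against Sham-NT with 1 library left out. Of the 17, 13 and 21 lists, 15, 7 and 10 stayed called whichever library was left out. Mouse numbers did not pair the libraries throughout: same-number correlations ran from -0.292 to 0.379, 8 of 12 over 0.1. Only 3 of 12 libraries correlated best with their own number, no more than chance would give. The highest correlation between groups, 0.512, joined Sham-NT 3 and TAC-BacNav 4. Same-number pairs ran from 0.115 to 0.375 for number 1, -0.020 to 0.203 for number 2, -0.292 to 0.175 for number 3 and 0.127 to 0.379 for number 4, so a partial pairing stays open. With the number as a block the calls were 889, 6 and 12, with 4 in opposite directions. Of 3308 values of named genes under 27 alternatives 2635 held their direction and side of the threshold, 604 lost and 42 gained a call, and 27, none of them a called value, changed sign. In TAC-mScarlet against Sham-NT Slc8a1 was 0.0182 on the low side. In TAC-BacNav against TAC-mScarlet Slc8a1 was -0.0592 on the low side, Camk2d 0.00089 with the block, 0.00030 with limma-voom, 0.0323 on the high side and -0.0542 to 0.0339 with 1 library left out, Pln -0.0018 to 0.203 and Cpt1b -0.114 to 0.828. In TAC-BacNav against Sham-NT Pln was 0.0654 and Kcnd2 0.0334 on the high side, Slc8a1 -0.0410 on the low side, Gja1 0.0823 by library size, 0.0510 with the length covariate, 0.0787 with a surrogate variable, 0.0013 at equal depth and 0.217 on the high side, and with 1 library left out Slc8a1 ran from -0.0121 to 0.131, Gja1 from -0.182 to 0.137 and Ppargc1a from -0.390 to 0.0332. Depth of 5.36 to 11.5 M limits genes near 1 CPM, and 1.5-fold changes were recovered for 15.9% of simulated genes. For Cpt1b, also near 1 CPM, the overlap of its exons with another gene makes the count itself uncertain.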

Other observations

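The genes of the GTPase family and of the depth split below were chosen after their values were seen. Other lists fixed in advance held single genes called between TAC-mScarlet and Sham-NT. Among 13 atrial and sinus node markers tested, from a list of 18, Nppa, Dkk3 (2.86 ± 0.64) and Pam (1.08 ± 0.24), which encodes an enzyme that amidates peptides, rose, and 4 up and 2 down were called adjusted over the list alone (median 0.49, camera adjusted p = 0.0923). Among 8 skeletal muscle markers tested, from a list of 15, Acta1 and Neb, the giant thin filament protein nebulin (1.44 ± 0.40), rose, the same 2 adjusted over the list alone (adjusted p = 0.120). Of 6 nerve and Schwann cell markers tested, from a list of 15, 2 fell, among them Dbh, the enzyme that makes noradrenaline (-2.06 ± 0.43, adjusted p = 0.0233, edgeR with Benjamini-Hochberg adjustment), and Prnp rose (0.72 ± 0.17), the same genes adjusted over the list alone (adjusted p = 0.388). Of 5 adipocyte markers tested, from a list of 13, the lipid droplet genes Plin4 (-0.79 ± 0.19) and Pnpla2 (-0.45 ± 0.12) fell, 3 adjusted over the list alone (median -0.49, adjusted p = 0.0156, and adjusted p = 0.238 with an estimated correlation). The list's call thus rests on a minority of its markers. The unfolded protein response gene Herpud1 (-0.94 ± 0.19), the autophagy gene Map1lc3a (-0.66 ± 0.17) and the apelin gene Apln (-0.97 ± 0.27) fell and the interferon-inducible Ifit2 (0.71 ± 0.18) rose in lists that were not called. Immediate early genes had a median of 1.23 in this comparison (adjusted p = 0.00103, and adjusted p = 0.460 with an estimated correlation), with 3 of 4 TAC-mScarlet and 2 of 4 Sham-NT libraries on the high side of their split. Inflammatory genes had a median of 0.53, 0.95 without Sham-NT 1 and 1.08 without Sham-NT 2, and were not called without Sham-NT 3 (3 up and 1 down adjusted over the list alone, adjusted p = 0.0196, and adjusted p = 0.457 with an estimated correlation).

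Interferon-inducible GTPase genes BC023105, Gm4841 and Igtp had higher CPM in each TAC-BacNav library than in any TAC-mScarlet library, without being called in the fit of all 3 groups. BC023105 was at 14.997, 5.79, 11.7 and 6.25 CPM in the TAC-BacNav libraries and at 1.79, 1.02, 1.25 and 0.928 CPM in TAC-mScarlet, with 10.5, 2.15, 2.59 and 0.801 CPM in Sham-NT (log2 fold change 2.94 ± 0.60, adjusted p = 0.780). Gm4841 was at 24.8, 5.07, 41.2 and 12.2 CPM against 4.30, 0.680, 1.25 and 0.580 CPM (3.61 ± 0.83, adjusted p = 1.00), and Igtp gave 1.31 ± 0.24. None of these passed edgeR's test with Benjamini-Hochberg adjustment in the fit of all 3 groups, but edgeR called BC023105 and Gm4841 with mouse number as a block and BC023105 with only these groups, and DESeq2 called BC023105 and Igtp. Reads of these similar genes cannot be assigned with certainty. Other members gave 0.47 ± 0.14 (Irgm2), 0.40 ± 0.21 (Irgm1), 0.24 ± 0.22 (Iigp1) and 0.32 ± 0.16 (Gbp2). The interferon list had a median of 0.11 (camera adjusted p = 0.0189, adjusted p = 0.768 with an estimated correlation, exact permutation p of the score 0.429), and its call was lost without TAC-mScarlet 1, TAC-mScarlet 2, TAC-mScarlet 4, TAC-BacNav 3 or TAC-BacNav 4, while its median was 0.33 without TAC-mScarlet 3.

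The split of Sham-NT and TAC-BacNav libraries by depth called 611 genes, 251 higher and 360 lower in the 4 deeper libraries (Sham-NT 3 and TAC-BacNav 1, 2 and 4), which are mostly of one group, of which 42 were among the 719. The splicing kinase genes Clk1 (-0.77) and Clk4 (-0.71), Ccnl2 (-0.77), Srsf6 (-0.57) and the ribosomal gene Rps28 (-0.76) were lower in the deeper libraries, and Tmod1 (1.58), Pstpip2 (1.36) and Selenop (0.87) higher. Median exon length was 4667 bases for the higher and 3527 for the lower genes. The same split moved the fatty acid list by -0.05 and the collagen list by 0.02, against -0.52 and 1.52 between TAC-mScarlet and Sham-NT.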
